A study of Mus musculus with 18 samples.

How the data were processed

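Liver RNA of 3 groups of male C57BL/6 mice was measured on 2 platforms, with 9 mRNA arrays and 9 miRNA arrays labelled as the same 9 mice, 3 per group. The authors' mRNA values are spot intensities from Agilent Feature Extraction 11.0.1.1, per the file headers, from 1-colour Cy3 scans of a whole mouse genome array whose design was annotated on mm9. The processed intensity had background subtracted with spatial detrending and multiplicative detrending, per the file headers. The deposited miRNA values are, per the file headers, foreground intensity and foreground minus background intensity of Hy3-labelled RNA, with replicate spots already combined. Their normalized column is a ratio made by the authors from foreground minus background divided by 1 number per array; that number equals the median over the 368 probes at 30 or more on all 9 arrays, to a relative deviation of at most 2.64e-07. The scanner software of the miRNA arrays is not stated in the labels or headers. All log2 values were computed here from the deposited intensities.

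Each mRNA array holds 44397 spots, of which 1377 are controls and were left out. The remaining 43020 carry 39429 probes with 33258 systematic names, of which 21460 matched a symbol in the reference table, used for names only; 12201 probes kept the file's name. The main values are log2 processed signal minus each array's 75th percentile. Spots marked as non-uniform or population outliers were set to missing, spots of a probe were averaged, probes were kept when well above background on all arrays of at least 1 group, and a gene took its brightest probe, which left 24814 genes. No mRNA spot was saturated. The columns did not hold a mean signal, so the normexp alternative (offset 50, then quantile normalization) used the median signal and its background.

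Before any test, arrays of a group were compared with the noise between repeated spots of a probe. Pairs averaged here had a ratio to that noise of 0.315 to 1.00 across brightness classes, and other pairs 1.61 to 3.48. Arrays simulated from the same RNA gave ratios of 0.501 to 0.853, and from different RNA 1.60 to 2.69. The difference between simulated samples was a chosen multiple of the spot noise, which sets the gap between these ranges. The simulation therefore does not show whether separate but similar samples could lie under the limit. MCT 330 replicate 1 exceeded that range for the same RNA against replicate 2 (1.005, also above the limit of 1) and replicate 3 (0.989, with 28 probes over 1 log2 unit apart). It was joined to them through replicate 3, so this join is less certain than the others. Before averaging, 75 spots of MCT 330 replicate 1 that lay over 1 log2 unit from both other arrays were left out. The design written in advance fitted the 9 mRNA arrays as 9 samples. It was replaced by a fit of 5 samples because the arrays turned out not to be independent, and the 9-array fit is given as an alternative. The MCT 330 group is then 1 sample, whose spread is taken from the other groups. The number of arrays limits the precision.

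Groups were compared with limma 3.58.1 (lmFit and eBayes, a single fit over the 3 groups) in R 4.3.3, with Benjamini-Hochberg adjusted p under 0.05 as the threshold. For a gene not well above background on any array of a group, a bound is given: the bright group against, per array, the higher of the lowest signal well above background and the gene's own. Genes were ranked on the bound of group means, and the text prints that of the nearest single samples. The 40 gene lists of pathways and cell type markers (1145 symbols, 1110 on the array), 7 groups of miRNAs and 15 families with targets were fixed before the data were examined. Lists were tested with camera at a preset correlation of 0.01, adjusted over the 40 lists, with an estimated correlation and fry beside it. In the 330 mg/kg comparisons the lists, like the genes, rest on 1 treated sample. Some lists share members: 21 of 30 periportal genes and 17 of 46 genes of gluconeogenesis and amino acid catabolism stand in another list.

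The miRNA values are foreground and background corrected with normexp (offset 50), quantile normalized on the log2 scale. Of 1178 probes, 1122 are named for mouse miRNAs and 56 for viral ones. Mouse probes at 30 or more over background on all arrays of at least 1 group were tested, 490 in all. The authors' normalized values took a pseudocount of 0.00571, the 5th percentile of positive values. Quantile ranking gave miR-690 and miR-709 an SD of 0 at MCT 270.

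Genes were named by rule: per dose the 10 highest and 10 lowest log2 fold changes that passed with all treated arrays beyond all controls, 5 and 5 between the doses, and up to 4 members per list (where fewer than 2 passed, those with the smallest p, as values). Clone and predicted names were left out, and some genes that the rule names are not reported here. After the values were seen, ranking was limited to genes well above background on all arrays of both groups, with bounded genes ranked apart; the genes of the plots by sample, and Cyp2e1, were also chosen after the values were seen. For miRNAs the 10 highest and 10 lowest and the fixed groups were open to naming.

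Simulated data tested each step. With 8000 changed genes the 270 mg/kg comparison recovered 74.6% of those changed by 1 log2 unit and 98.6% at 3, and the 330 mg/kg comparison 92.7% at 2; with 200 changed genes the 270 mg/kg comparison recovered 0% at 1 and 84% at 3. Camera called 8 of 8 lists moved by 0.5 log2 units, with 1 other call. The simulated genes were drawn independently, so this does not test the preset correlation for genes that move together. For 60 changed miRNAs the 270 mg/kg comparison recovered 65% at 1 and 95% at 2.

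Alternatives covered background correction, normalization, filters, probes per gene, the variance model, samples in the fit, replicate number, slide and scan day as blocks, and each array left out. Slide 1 holds control and MCT 270 replicates 1 and 2, and slide 2 holds their replicates 3. MCT 330 lies on 2 slides of its own, so slide cannot be told apart from 330 mg/kg. Scan day 1 holds replicates 1 and 2 of each group. Scan day and slide blocks, fitted on 9 arrays, were planned. The fit of 9 arrays written in advance, kept as an alternative with and without the replicate block, a random block for the independent sample, keeping the masked spots, results within slide 1, lists under normexp, averaged miRNA arrays and leaving out averaged samples became alternatives after seeing the data. Values and plots were made with the packages data.table (version 1.17.8), Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.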

Results

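Monocrotaline is a plant pyrrolizidine alkaloid that hepatic cytochrome P450 enzymes turn into a reactive pyrrole, and that is known for injuring the sinusoidal endothelium of the liver. Male C57BL/6 mice of 6 weeks received 1 oral dose of 270 or 330 mg/kg (MCT 270, MCT 330) or saline (control) after 12 h without food, 8 mice per group, and livers were taken 48 h later. Messenger RNA was profiled on 9 single-colour whole mouse genome arrays and microRNA (miRNA) on 9 single-colour arrays, labelled as the same 3 mice per group. Between 64.0% and 80.9% of mRNA probes lay well above background per array, the 75th percentile of signal ranged from 498.2 to 703, and between 435 and 510 mouse miRNA probes reached a signal of 30 over background. The number of arrays limits the precision.

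The 9 mRNA arrays held 5 distinguishable liver samples. Replicates 2 and 3 of the control and of the MCT 270 group, and all 3 replicates of the MCT 330 group, differed from one another by an SD of 0.0219 to 0.0430 on the log2 scale over 23369 probes, against 0.0583 between repeated spots of a probe on 1 array. Replicate 1 of the control and of the MCT 270 group differed from its group's other arrays by an SD of 0.165 to 0.174. Arrays joined by pairs no further apart than repeated spots (a highest ratio of 1 over brightness classes) were averaged; MCT 330 replicates 1 and 2 lay at 1.005, with 27 probes over 1 log2 unit apart, and were joined through replicate 3. That left 2 control samples, 2 MCT 270 samples and 1 MCT 330 sample. The labels describe separate mice. The limma p-values of single mRNA genes measure the spread between these 5 samples, and the lone MCT 330 sample is assumed to vary like the other groups. Camera p-values of lists at the preset correlation measure the spread across genes, not between samples. The 9 miRNA arrays (SD within groups 0.189 to 0.427) could not be tested in this way, because their spots were deposited already combined. Replicates 2 and 3 were the closest pair in each group there too (SD 0.282, 0.189 and 0.224), so repeated samples are not excluded. The miRNA arrays entered as 3 samples per group, as labelled.

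**Figure D1:**
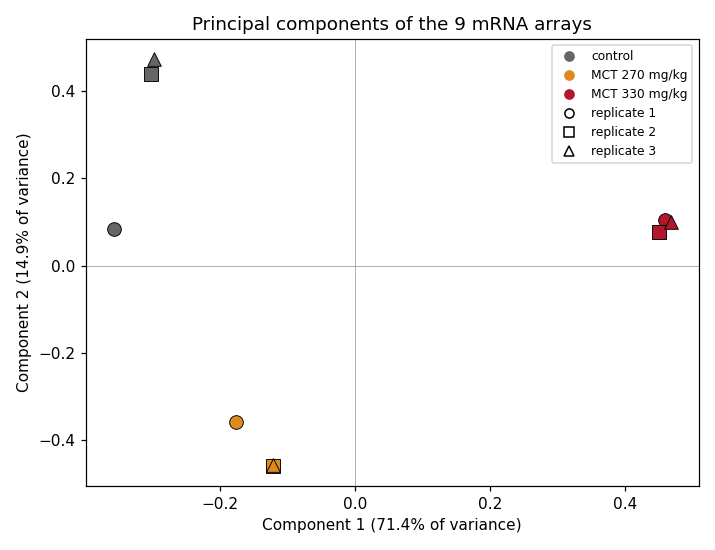
Principal components of the 9 mRNA arrays, from log2 signal (colours are groups, shapes are replicates). Coordinates on each component are scaled to unit length, so distances along the 2 axes do not reflect their shares of variance. Component 1 holds 71.4% and component 2 holds 14.9% of the variance, and the arrays fall into 5 clusters.

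The first comparison asks how the liver at 270 mg/kg differed from control. Pericentral hepatocyte genes were lower: Glul, the glutamine synthetase of the hepatocytes around the central vein, differed from control by a log2 fold change of -3.43 ± 0.37 (SE, n = 2 and 2) and the glutamate transporter Slc1a2 by -3.10 ± 0.28. Markers of liver sinusoidal endothelium were lower, with Stab2, a scavenger receptor, at -2.28 ± 0.16 and the nuclease Dnase1l3 at -1.68 ± 0.19. The p53 target Phlda3 lay at 2.91 ± 0.22, and G6pdx, the Nrf2-responsive first enzyme of the pentose phosphate pathway, at 3.23 ± 0.17. As single genes, 0 of 24814 passed limma's test after Benjamini-Hochberg adjustment (lowest adjusted p 0.0598). At an unadjusted p under 0.05, 4612 genes stood out, of which 2434 were higher and 2178 lower.

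As groups, 17 of 40 fixed lists were called at MCT 270 by camera, limma's test of a list against all other genes. The pericentral genes fell (camera adjusted p = 2.42e-07), and 15 of 32 members were lower and 2 higher when adjusted over the list alone, against 0 over all genes. PPAR-alpha targets and fatty acid oxidation genes fell (6 of 42 lower adjusted over the list alone, adjusted p = 0.000124). Among them the acyl-CoA thioesterase Acot1 lay at -2.48 ± 0.26. Male-biased liver genes fell (1 of 32 lower adjusted over the list alone, adjusted p = 0.000282), but this call rests on control replicate 1: without it the relative median went from -0.57 to -0.12 (adjusted p = 0.152). Complement components (0 of 25 adjusted over the list alone, adjusted p = 0.0327) and plasma carrier proteins (1 of 36 higher and 2 lower adjusted over the list alone, adjusted p = 0.0355) were also called lower, although the thyroxine carrier Serpina7 lay at 3.21 ± 0.38. With an estimated correlation in place of the preset one, the adjusted p was 0.847 for each of these lists.

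Lists of non-parenchymal cells fell too, with counts again adjusted over the list alone and 0 over all genes. Of 22 sinusoidal endothelial markers 12 were lower (camera adjusted p = 7.38e-07). Of 25 pan-endothelial markers 9 were lower and 1 higher (adjusted p = 0.00446), with the phosphatase Ptprb at -1.61 ± 0.19. Of 24 stellate cell markers 10 were lower and 2 higher (adjusted p = 0.00663), with Angptl6 at -1.80 ± 0.16 and the lectin Colec11 at -1.53 ± 0.18. Of 20 Kupffer cell markers 6 were lower and 1 higher (adjusted p = 0.0102), with the complement receptor Vsig4 at -1.39 ± 0.18. T cell markers (2 of 19 lower, adjusted p = 0.0441) and extracellular matrix genes (5 of 45 lower and 2 higher, adjusted p = 0.0465) were called as well. Each of these lists had an adjusted p of 0.847 with an estimated correlation.

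Stress and clock genes were higher at MCT 270, with counts adjusted over the list alone and 0 over all genes. The p53 targets rose as a list (13 of 40 higher and 1 lower, camera adjusted p = 1.89e-05), with Zfp365 at 2.20 ± 0.17. Nrf2 and glutathione genes rose (8 of 34 higher, adjusted p = 0.000124), with the carbonyl reductase Cbr3 at 1.74 ± 0.18. Type I interferon response genes rose (6 of 38 higher, adjusted p = 0.00153), with the nucleic acid sensor Zbp1 at 1.47 ± 0.15. Circadian clock genes rose (8 of 18 higher and 2 lower, adjusted p = 0.00312), with Dbp, a clock output factor, at 2.41 ± 0.26 and Nfil3, its repressing counterpart, at -2.07 ± 0.20. Coagulation initiation and fibrinolysis regulators rose (4 of 17 higher and 1 lower, adjusted p = 0.00588), with the protein C receptor Procr at 1.49 ± 0.19, and so did heat shock genes (0 of 17 alone, adjusted p = 0.0218). The adjusted p was 0.847 with an estimated correlation for each of these lists. Of all 40 lists fry, limma's rotation test of a list's own direction, called the clock genes (fry adjusted p = 0.0416) and no other.

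Of the 23 lists not called at MCT 270, ER stress and integrated stress response (camera adjusted p = 0.0604) and cholesterol synthesis (0.0740) came nearest; ER stress (0.0424 and 0.0281) and acute phase proteins (0.0363 and 0.0301) were called with quantile normalization and with normexp background correction followed by quantile normalization (normexp below). Drug-metabolising P450s (median log2 fold change -0.15, adjusted p = 0.701) and phase II conjugation enzymes (-0.04, 0.756) were not called, nor were gluconeogenesis and amino acid catabolism (0.892), neutrophil markers (0.287), cytokines and chemokines (0.458) or immediate early genes (0.413). Median, mean and test differed in sign for P450s, fatty acid synthesis, female-biased genes and exocrine pancreas markers. The count of 0 genes became 519 with normexp and 9544 when the 9 arrays were counted as separate samples. Matrix, complement, T cell, plasma carrier and Kupffer lists lost their call in 10, 5, 5, 4 and 3 of 15 alternatives. For plasma carriers the relative median went from -0.13 to -0.01 with either scaling (adjusted p = 0.609 with quantile normalization and 0.589 with normexp).

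The next comparison asks what 330 mg/kg changed. Sprr1a rose by a log2 fold change of 6.44 ± 0.22 (SE, 1 sample against 2; limma adjusted p = 0.00899), the stress transcription factor Atf3 by 6.04 ± 0.40, the neutrophil proteins S100a8 by 5.81 ± 0.49 and S100a9 by 5.57 ± 0.63, and the monocyte-attracting chemokine Ccl2 by 5.37 ± 0.59. The neutrophil-attracting Cxcl1 (5.40 ± 0.61), Bcl2l14 (5.31 ± 0.21), the iron-scavenging Lcn2 (5.27 ± 0.77) and the immediate early gene Fos (4.67 ± 0.21) also stood among the 10 highest. The genes that fell most included the male-biased steroid enzyme Hsd3b5 at -8.05 ± 1.20 (adjusted p = 0.0137), the anion transporter Slco1a1 at -5.56 ± 0.57, the hepcidin gene Hamp2 at -5.45 ± 1.21, the fatty acid hydroxylases Cyp4a12a at -5.10 ± 0.74 and Cyp4a12b at -4.69 ± 0.68, and the corticosteroid carrier Serpina6 at -4.37 ± 0.44. Nox4 (-6.88 ± 0.71), Tmtc2 (-5.33 ± 0.40), the stellate cell retinol enzyme Lrat (-4.45 ± 0.41) and Bbs9 (-4.38 ± 0.20) also stood among the 10 lowest. Genes not well above background in 1 group have a bound, given here between the nearest single samples: the chemokine Ccl7 was at least 23.9-fold higher, and the fatty acid elongase Elovl3 at least 68.6-fold and Susd4 at least 12.8-fold lower. The 2 controls were far apart in several of these genes, by an SD on the log2 scale of 2.75 for Elovl3, 2.09 for Hsd3b5, 1.38 for Susd4, 1.27 for Cyp4a12a, 1.21 for Hamp2, 1.16 for Cyp4a12b and 1.09 for Nox4. Without control replicate 1 Hsd3b5 lay at -6.57, Hamp2 at -6.31 and Nox4 at -6.11. Slco1a1 then lay at -4.88, Cyp4a12a at -4.20 and Cyp4a12b at -3.87, while Serpina6 moved further from 0, to -4.87.

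**Figure D2:**
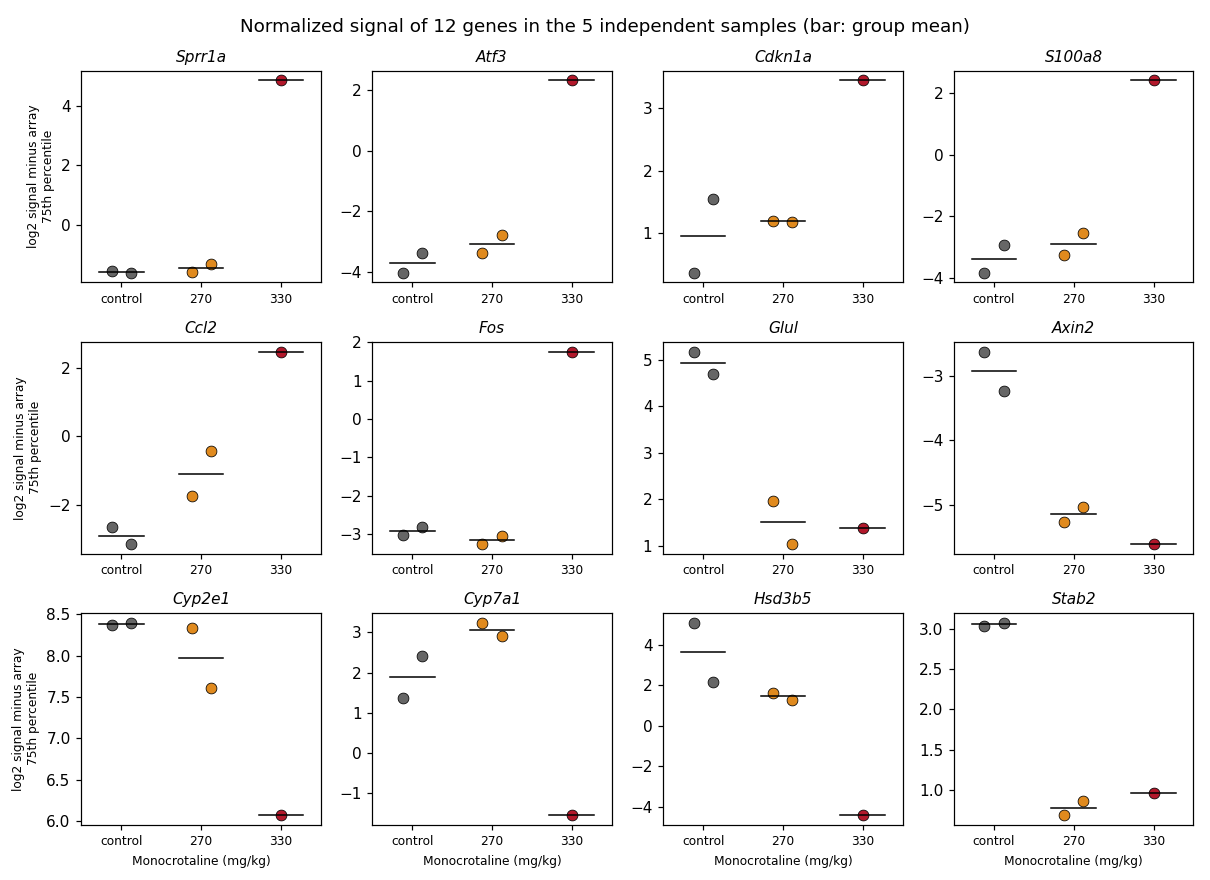
Signal of 12 genes in the 5 independent samples (log2 signal minus the array's 75th percentile; points are samples, bars are group means, each panel has its own scale). Glul and Stab2 lie lower in both MCT 270 samples and in the MCT 330 sample, whereas Fos and Cyp2e1 differ mainly at MCT 330.

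Limma called 8273 of 24814 genes at MCT 330, 2363 higher and 5910 lower, and 6621 of them by at least 2-fold. The median of all genes lay at -0.25, so list medians are given relative to it. With quantile normalization 3101 rose and 4286 fell, with normexp 3732 rose and 3947 fell, and the medians of all genes were -0.05 and -0.03. The call rests on 1 sample, and on the spread within the other groups: leaving out MCT 270 replicate 1 gave 4905 genes, and counting the 9 arrays as separate samples gave 18051.

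Hepatocyte genes fell at MCT 330 in most lists. Of 32 pericentral genes 26 fell and 1 rose over all genes, and the same counts held adjusted over the list alone (relative median -1.89, camera adjusted p = 7.90e-06). They included Glul at -3.55 ± 0.46, the R-spondin receptor Lgr5 at -3.42 ± 0.74 and Rgn at -3.24 ± 0.20, while the glutathione transferase Gstm3 rose. Of 30 periportal genes 12 fell and 1 rose (14 and 1 adjusted over the list alone, relative median -0.62, adjusted p = 0.0107), with Etnppl at -2.33 and the urea cycle enzyme Otc at -2.13. Of 37 P450s and flavin monooxygenases 17 fell (19 lower and 1 higher adjusted over the list alone, adjusted p = 0.00587), led by Cyp1a2 at -2.83 ± 0.25 and Cyp2c39 at -2.65. Of 26 phase II enzymes 9 fell (11 adjusted over the list alone, adjusted p = 0.00806), with the methyltransferase Inmt at -2.89 ± 0.31. Of 19 bile acid synthesis genes 11 fell (13 adjusted over the list alone, adjusted p = 0.000811), with Cyp8b1 at -4.16 ± 0.52 and Cyp7a1, the rate-limiting enzyme, at -3.43 ± 0.48. With an estimated correlation the adjusted p of these 5 lists lay between 0.562 and 0.629.

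Metabolic and secretory lists followed. Of 42 PPAR-alpha targets and fatty acid oxidation genes 24 fell (28 lower and 1 higher adjusted over the list alone, camera adjusted p = 0.000114), with the peroxisomal thiolase Acaa1b at -2.69. Of 46 genes of gluconeogenesis and amino acid catabolism 20 fell (23 adjusted over the list alone, adjusted p = 0.000152), with glucose-6-phosphatase G6pc at -3.76 ± 0.78. Of 32 male-biased genes 16 fell (17 adjusted over the list alone, adjusted p = 0.000344). Of 28 coagulation proteins made by hepatocytes 10 fell and 1 rose (12 and 1 adjusted over the list alone, adjusted p = 0.0225), with factor F5 at -1.66 and prekallikrein Klkb1 at -1.56. Of 36 plasma carrier proteins 12 fell, and Serpina7 rose by 4.19 ± 0.47 (the same counts adjusted over the list alone, adjusted p = 0.0225). The coagulation and carrier calls ended with quantile normalization (adjusted p = 0.0965 and 0.0827; relative medians -0.39 to -0.34 and -0.24 to -0.09). These 5 lists had an adjusted p of 0.572 to 0.629 with an estimated correlation.

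Stress programmes rose. Of 27 immediate early genes 21 rose and 1 fell (23 and 2 adjusted over the list alone, camera adjusted p = 1.24e-13), with Ier3 at 5.28 ± 0.29. Of 40 p53 targets 24 rose and 1 fell (25 and 1 adjusted over the list alone, adjusted p = 1.19e-11), with Phlda3 at 4.64 ± 0.27, the stress cytokine Gdf15 at 4.23 ± 0.34 and the growth arrest gene Gadd45a at 3.85 ± 0.55. Of 34 Nrf2 and glutathione genes 15 rose, the same adjusted over the list alone (adjusted p = 0.000114), with G6pdx at 3.71 ± 0.21 and haem oxygenase Hmox1 at 2.82 ± 0.28. Of 35 ER stress genes 5 rose (4 adjusted over the list alone, adjusted p = 0.000709), with Nupr1 at 2.92 ± 0.46 and Ddit3 at 2.20 ± 0.19. Of 17 heat shock genes 5 rose, the same adjusted over the list alone (adjusted p = 0.00229), with Hsp90aa1 at 1.50 ± 0.35. Of 38 interferon response genes 9 rose (3 adjusted over the list alone, adjusted p = 8.06e-06), with Zbp1 at 2.14 ± 0.19 and Irf7 at 1.66. The 6 lists had an adjusted p of 0.562 to 0.567 with an estimated correlation.

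Inflammatory and clotting lists rose. Of 25 neutrophil markers 13 rose and 1 fell (13 and 3 adjusted over the list alone, camera adjusted p = 8.99e-06), with Retnlg at 5.68 ± 0.34. Of 28 monocyte and recruited macrophage markers 11 rose and 2 fell (13 and 3 adjusted over the list alone, adjusted p = 1.03e-05), with the lectin Clec4d at 4.50 ± 0.31 and Chil3 at 4.04 ± 0.39. Of 39 cytokines and chemokines 15 rose and 5 fell (16 and 6 adjusted over the list alone, adjusted p = 7.63e-05). Of 36 acute phase proteins 15 rose and 2 fell (16 and 2 adjusted over the list alone, adjusted p = 8.06e-06), with serum amyloid Saa1 at 4.53 ± 1.13. Of 17 coagulation initiation and fibrinolysis regulators 10 rose and 1 fell (11 and 3 adjusted over the list alone, adjusted p = 7.63e-05), with thrombospondin Thbs1 at 4.65 ± 0.76 and the urokinase receptor Plaur at 3.82 ± 0.30. Each of these 5 lists had an adjusted p of 0.562 with an estimated correlation.

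Resident sinusoidal cell markers went the other way. Of 22 sinusoidal endothelial markers 12 fell, the same adjusted over the list alone (camera adjusted p = 0.000412), with Ehd3 at -3.78 ± 0.30, Clec4g at -3.45 ± 0.29 and the mannose receptor Mrc1 at -2.84 ± 0.22. Of 25 pan-endothelial markers 13 fell and 1 rose (14 and 2 adjusted over the list alone, adjusted p = 0.0140), with Rspo3, a Wnt enhancer made by central vein endothelium, at -2.03 ± 0.23. Of 24 stellate cell markers 12 fell and 1 rose (13 and 3 adjusted over the list alone, adjusted p = 0.0247), with Angptl6 at -2.58. The adjusted p of these 3 lists was 0.562 with an estimated correlation. Kupffer cell markers were not called as a list (7 of 20 fell and 1 rose, 9 and 2 adjusted over the list alone, adjusted p = 0.121, and 0.0409 with normexp), although Vsig4 fell to -2.64 ± 0.22 and Clec4f to -2.53 ± 0.25.

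Of the 16 lists not called at MCT 330, complement components (7 of 25 fell, camera adjusted p = 0.0512), bile acid and anion uptake with canalicular export (9 of 17 fell and 1 rose, adjusted p = 0.0619, and 0.0314 with normexp) and exocrine pancreas markers (6 of 14 fell, adjusted p = 0.0620) came nearest. Cholesterol synthesis (8 of 26 fell and 1 rose, adjusted p = 0.349) and fatty acid synthesis (7 of 23 fell and 2 rose, adjusted p = 0.249) were not called, and of the 7 basolateral export transporters Abcb1b (2.23 ± 0.33) and Abcc1 (1.68 ± 0.22) rose (adjusted p = 0.164). Matrix genes moved both ways (9 of 45 rose and 13 fell, adjusted p = 0.368), female-biased genes fell in 3 of 24 (adjusted p = 0.874), and clock genes rose in 2 of 18 and fell in 1 (adjusted p = 0.314). Median, mean and test differed in sign for cell cycle, T cell, matrix, clock, erythroid and female-biased lists. For 57 genes probes of the same gene were called both ways. Of the genes named, Nkg7 and Sctr had another probe that lay the other way without a call. Fry called 12 lists, among them 10 of the 24 that camera called; Nrf2 genes (fry adjusted p = 0.0775) and interferon response genes (0.170) were not called by fry.

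**Figure D3:**
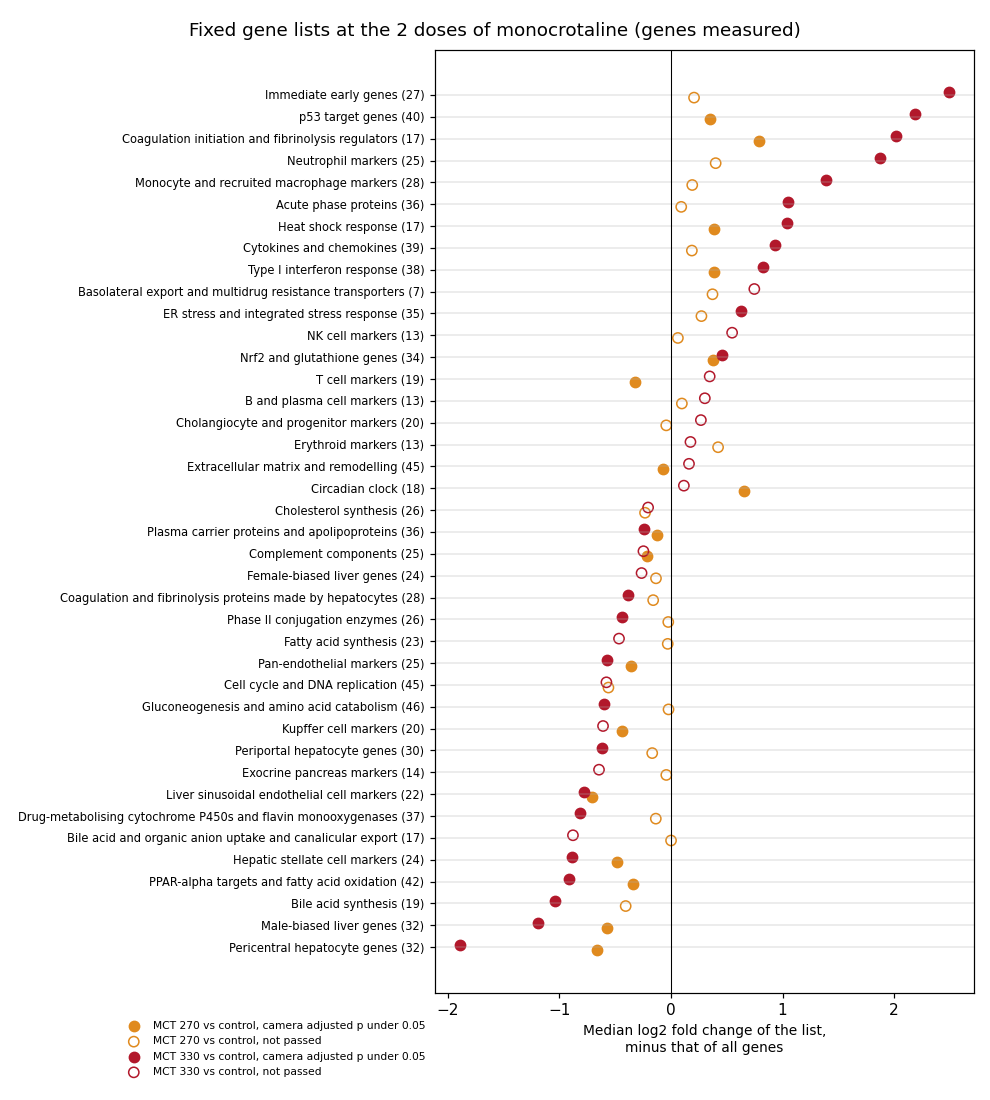
Median log2 fold change of the 40 fixed lists minus that of all genes (x axis; numbers of measured genes in brackets), for MCT 270 and MCT 330 against control, with filled points for a camera adjusted p under 0.05. Pericentral genes lie lowest at MCT 330 (-1.89) and immediate early genes highest (2.49).

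The third comparison asks how the doses differed. From MCT 270 to MCT 330 the genes that rose most included Sprr1a by 6.32 ± 0.22 (1 sample against 2; limma adjusted p = 0.0209), Atf3 by 5.42 ± 0.40, S100a9 by 5.36 ± 0.63 and S100a8 by 5.32 ± 0.49. Those that fell most were Hsd3b5 at -5.88 ± 1.20, Cyp7a1 at -4.61 ± 0.48, Lrat at -4.22 ± 0.41, Slco1a1 at -3.90 ± 0.57 and Serpina6 at -3.85 ± 0.44. Glul (-3.43 and -3.55 against control) and Slc1a2 (-3.10 and -3.38) were not called between the doses (limma adjusted p = 0.882 and 0.602), whereas Rgn fell further (-2.45 ± 0.20), as did Cyp2e1, the ethanol-inducible P450 (-1.90 ± 0.34). Limma called 5417 genes, 1245 higher and 4172 lower; quantile normalization gave 1503 higher and 2369 lower, and normexp 1990 and 2051.

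Of 40 lists 23 were called between the doses, 13 up and 10 down; quantile normalization gave 9 up and 13 down and normexp 9 up and 15 down, so the balance turns with the scaling. Immediate early genes rose (20 of 27, and 22 adjusted over the list alone, camera adjusted p = 1.69e-17), with Fos at 4.91 ± 0.21 and Jun at 4.41 ± 0.35. The p53 targets rose (20 of 40, and 23 with 2 lower adjusted over the list alone, adjusted p = 5.54e-11), with Btg2 at 2.97 ± 0.32. Neutrophil markers (11 of 25 rose and 1 fell, 12 and 2 adjusted over the list alone, adjusted p = 1.94e-07) and monocyte markers (9 of 28 rose, 13 and 1 lower alone, adjusted p = 7.85e-07) rose. So did acute phase proteins (9 of 36 rose, 10 alone, adjusted p = 1.50e-07), cytokines (13 of 39 rose and 3 fell, 15 and 3 alone, adjusted p = 1.78e-06) and coagulation initiation (7 of 17 rose and 1 fell, 10 and 3 alone, adjusted p = 5.00e-05). Gluconeogenesis and amino acid catabolism fell (16 of 46, and 27 adjusted over the list alone, adjusted p = 7.66e-06), as did P450s (12 of 37, 15 alone, adjusted p = 0.000207) and bile acid synthesis (8 of 19, 11 alone, adjusted p = 0.000604). Phase II enzymes (5 of 26, 11 alone, adjusted p = 0.00194) fell, and pericentral genes (14 of 32, 18 alone, adjusted p = 0.00221) fell further. Smaller calls upward were interferon response (adjusted p = 0.00113), ER stress (0.0305), T cell (0.0305), cell cycle (0.0314), matrix (0.0314) and heat shock (0.0371). Those downward were PPAR-alpha (adjusted p = 0.0142), periportal (0.0169), male-biased (0.0337), exocrine pancreas (0.0337) and uptake transporter lists (0.0398). Fry called 2 of the 23, immediate early genes and neutrophil markers (fry adjusted p = 0.0381 for both). The 23 lists had a camera adjusted p of 0.457 to 0.727 with an estimated correlation.

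Sinusoidal endothelial (7 of 22 fell, camera adjusted p = 0.0984), pan-endothelial (0.101), stellate (0.0923) and Kupffer cell markers (0.598) were not called between the doses, nor were Nrf2 genes (0.0671) or, as a list, clock genes (0.857), although Dbp fell (-2.71 ± 0.32). With normexp the sinusoidal endothelial (adjusted p = 0.0348), pan-endothelial (0.0380) and stellate lists (0.0211) were called lower, and with quantile normalization the pan-endothelial list was (0.0466), so this negative result depends on the scaling. Median, mean and test differed in sign for the Nrf2, ER stress, NK, B cell and erythroid lists, and the median of matrix genes was 0.00. The gene count became 0 without MCT 270 replicate 1, with the replicate number as a block or without a filter on dim probes, and 16109 with the 9 arrays as separate samples. Cell cycle and heat shock lists lost their call in 5 of 14 alternatives each, ER stress and matrix lists in 4 and exocrine pancreas markers in 3.

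Across genes, which are not independent replicates, the log2 fold changes of the doses correlated with r = 0.588. Unchanged groups simulated against the same controls gave 0.411 (0.387 to 0.438 over 100 simulations). The covariance was 0.342 against 0.0366 simulated, a difference of 0.305. Of genes higher at MCT 270 at an unadjusted p under 0.05, 1028 were called higher at MCT 330 (232 for independent lists), and of those lower, 1377 were called lower (519 for independent lists). With 1 control sample for each dose, so that none was shared, r was 0.486 or 0.307, depending on which served which dose (covariance 0.315 or 0.214). The overlaps were counted with shared controls, which may add to them.

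**Figure D4:**
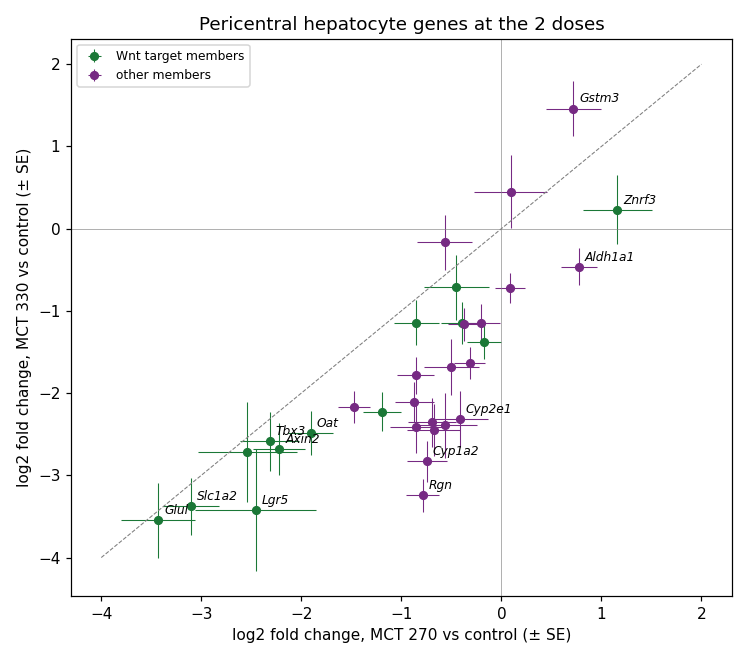
Log2 fold change against control of the 32 pericentral genes at MCT 270 (x axis) and MCT 330 (y axis), with SE bars and the line of equal values dashed. Colours set 13 members chosen as Wnt targets apart from 19 others. Glul, Slc1a2 and Tbx3 lie near the line, and Rgn, Cyp1a2 and Cyp2e1 lie below it.

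The miRNA arrays ask which small RNAs changed with each dose. At MCT 270 the highest were miR-137-5p at 3.50 ± 0.51 (log2 fold change ± SE, n = 3 and 3; limma adjusted p = 0.00271), miR-690 at 3.17 ± 0.59, miR-3084-5p at 2.61 ± 0.53, miR-691 at 2.52 ± 0.37 and let-7e-5p at 2.51 ± 0.34, followed by miR-181d-5p (2.33), miR-709 (2.27), miR-34c-3p (2.04), miR-3473a (1.99) and miR-124-3p (1.92). The lowest were miR-188-3p at -3.30 ± 0.46 (adjusted p = 0.00243), miR-493-5p at -2.60, miR-463-3p at -2.46, miR-743a-3p at -2.32 ± 0.25 and miR-878-3p at -1.92. Limma called 131 of 490 miRNAs, 78 higher and 53 lower. The authors' normalized values called 56 higher and 85 lower, and median scaling 44 and 56, so the balance of directions turns with the scaling.

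At MCT 330 limma called 26 of 490 miRNAs: miR-592-3p was higher (1.16 ± 0.28, n = 3 and 3; adjusted p = 0.0443) and 25 were lower, led by miR-188-3p at -3.23 ± 0.46, miR-743a-3p at -2.45, miR-878-3p at -2.43 ± 0.22 (adjusted p = 0.000416), miR-489-3p at -2.23 and miR-463-3p at -2.16. The call of miR-592-3p was lost in 14 of 20 alternatives. Both doses called 21 miRNAs, all lower, against 2.70 for independent lists; the shared controls may add to that overlap. Between the doses 30 were called: 6 were higher at MCT 330, among them miR-3102-5p (adjusted p = 0.0252; detected on 0 MCT 270 arrays, so no fold is given), miR-27a-3p (1.18 ± 0.26) and miR-351-5p (1.14), and 24 were lower, among them miR-137-5p (-2.51), let-7e-5p (-2.11), miR-181d-5p (-1.96), miR-34c-3p (-1.79) and miR-124-3p (-1.59). The authors' normalized values gave 39 higher and 31 lower between the doses, and median scaling 22 and 23. With replicates 2 and 3 of each group averaged the counts were 26, 12 and 0 in the 3 comparisons, and with arrays averaged as on the mRNA platform 0, 0 and 0, so the miRNA calls assume separate mice. Counts depended on single arrays: without control replicate 1 the MCT 270 count was 28, without control replicate 2 it was 36 and without MCT 270 replicate 3 it was 69, and the MCT 330 count lay between 12 (without control replicate 2) and 76 (without MCT 330 replicate 3).

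Among fixed miRNA groups, 9 hepatocyte-enriched miRNAs were detected and 0 were called by limma at either dose, over all miRNAs or adjusted over the list alone; miR-122-5p, the most abundant hepatocyte miRNA, lay at -0.61 ± 0.28 and -0.27 ± 0.28. The same held for 2 endothelium-enriched, 2 miR-200 family and 7 fibrosis-related miRNAs. Of the p53-induced miR-34 family, miR-34c-3p rose at MCT 270 and lay at 0.25 at MCT 330. At the 2 doses miR-34a-5p lay at 0.82 and 1.19 ± 0.41, and miR-34b-3p at 0.34 and -0.56. Adjusted over these 3 alone, 1 was higher at MCT 270, 1 was higher at MCT 330 and 2 were lower at MCT 330 than at MCT 270.

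**Figure D5:**
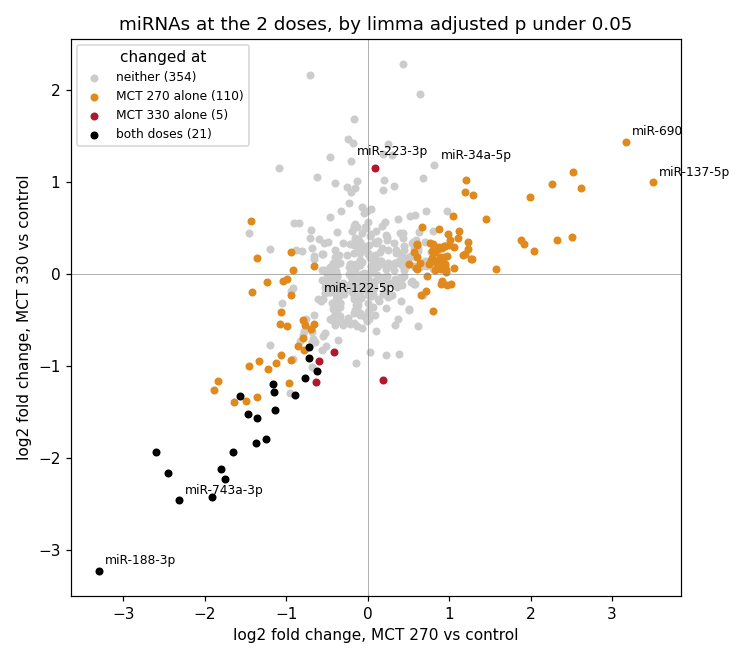
Log2 fold change of 490 miRNAs at MCT 270 (x axis) and MCT 330 (y axis) against control, coloured by limma's call. Both doses called 21 miRNAs, 270 mg/kg alone 110 and 330 mg/kg alone 5.

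The series title names the integration of miRNA and mRNA, so each of 15 miRNA families fixed with textbook targets was set against them, 14 of which were detected. Across families, Spearman's rho between family and median target change was 0.446 at MCT 270 (permutation p = 0.112, two-sided, 100000 resamples; Pearson's r 0.131, and 0.569 without the 2 farthest families) and -0.464 at MCT 330 (permutation p = 0.0966; r = -0.352, and -0.193 without them), with an adjusted p of 0.112 for both permutation tests. Relative to all genes, 6 families at MCT 270 and 10 at MCT 330 moved opposite to their targets. For miR-122 the family lay at -0.61 and -0.27 and its targets at 0.12 and 0.97 relative to all genes, and for miR-34 the family lay at 0.82 and 1.19 and its targets at -0.17 and -0.38. Others moved with their targets, such as miR-29 at MCT 270 (-0.36, targets -0.35) and the miR-17 family at MCT 330 (0.41, targets 1.17).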

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

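The tests of pericentral genes, of other cytomegalovirus probes and of clock genes were chosen after the result was seen; the test of probes that move alike and the splits of the miRNA arrays were chosen before.

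Pericentral genes fell further than periportal ones at both doses. The difference was -0.50 at MCT 270 (permutation of members, p = 0.0009) and -1.27 at MCT 330 (permutation p = 0.0004) on the log2 scale. These p-values measure the spread across members, which are not independent replicates, and not that between samples. In these samples the fall was thus not alike in the 2 zones, but the test cannot tell whether that holds for other mice. With an estimated correlation the pericentral list had a camera adjusted p of 0.847 at MCT 270. A smaller share of hepatocyte RNA, as the only change, would raise markers of every other cell type alike. At MCT 330 sinusoidal endothelial markers had a relative median of -0.78 (bootstrap interval -1.84 to -0.37) and neutrophil markers 1.87 (0.27 to 3.88). With normexp and quantile normalization these were -0.79 (-1.65 to -0.41) and 0.56 (0.14 to 1.50), further together but on the same sides of 0. So the share was not the only change. The test cannot exclude a smaller share, because monocrotaline injures the sinusoidal endothelium, whose markers could fall whatever the share of hepatocytes. The 13 pericentral members chosen here as Wnt targets were already low at MCT 270 (median -1.91, then -2.48 at MCT 330). The 19 others lay at -0.56 and then -1.79, and the change between the doses differed by 0.78 (permutation of members, p = 0.00435). Some of the others, Cyp2e1 and Cyp1a2 among them, may depend on Wnt as well. The split therefore does not set Wnt-dependent genes against independent ones. As a set the 13 were mostly low at the lower dose already, a pattern found and tested on the same data. The 13 were not uniform at MCT 270: Znrf3 lay at 1.16, Lect2 at -0.17, Notum at -0.39 and Rnf43 at -0.45. The values cannot tell a loss of the Wnt-dependent programme from a loss of the cells that express it. The Wnt targets Axin2 and Lgr5, unlike Glul and Oat, lay near background after treatment with little room to fall further. The MCT 330 values come from 1 sample, so a smaller hepatocyte share and an early loss of the Wnt-dependent programme both stay open.

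A probe for a viral miRNA of mouse cytomegalovirus, mcmv-miR-m108-1-3p, drew attention because it was outside the mouse probes tested and brighter at MCT 270 by a log2 fold change of 3.70 ± 0.44 (limma adjusted p = 0.00101; higher in 3 of 3 arrays). Infection would raise other probes of that virus, but the other detected one lay at -1.17, and of 28 others without a filter 0 rose and 2 fell (median 0.03). Deviations of the probe within groups followed those of the 10 mouse miRNAs that rose most, with a mean correlation of 0.80 against at most 0.56 in 10000 other sets. Those 10 correlated with one another at 0.69. The 10 that fell most also did, at 0.64 against at most 0.53 in other sets, and with the probe at -0.61. Sets drawn at random lack such covariation, so the test does not separate labelled RNA that binds several probes alike from a response that varies in strength between arrays, and the cause stays open.

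Clock genes shifted at MCT 270 and went both ways at MCT 330. In 13 of 14 clock genes with a known phase both MCT 270 samples lay beyond both controls in the direction another clock time would give (16.7% by chance for each gene). At MCT 330 Per2 lay at 1.38 ± 0.38 and Tef at -0.88 ± 0.19. A clock response that grows with dose would enlarge the shift, but of 13 clock genes well above background on all arrays 6 had a smaller shift at MCT 330 and 0 a larger one (limma adjusted p under 0.05). The shift is signed by phase, so a reversal beyond control counts as smaller. Of the 6, Dbp went from 2.41 to -0.29, Ciart from 1.82 to -0.14 and Nfil3 from -2.07 to -0.63. Tef (0.78 to -0.88), Hlf (0.37 to -0.89) and Usp2 (0.81 to -1.50) reversed to a larger distance from control. The lower signed shifts argue against a shift in the direction of phase that grows with dose. They do not show a return to control, members of 1 clock are not independent, and MCT 330 is 1 sample. Tissue taken at another clock time may account for the shift, but the hour of sampling is not given, and feeding, which also sets liver clocks, was not measured. Either could also contribute to other differences between MCT 270 and control, which was not tested.

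Of 255 named genes, 57 had opposite signs at the 2 doses with a tested difference, and 7 of these were at least 2-fold apart from control both ways. In 4 of the 7, each comparison with control held a group well above background on all its arrays, and these drew attention by limma's test of MCT 330 against MCT 270. Their values at MCT 270 did not pass on their own (adjusted p 0.0981 to 0.227), nor did that of Pdk4 at MCT 330 (0.114). Cyp7a1 differed by -4.61 (1.18 and -3.43 against control). The immediate early gene Egr1 differed by 4.30 (-1.14 and 3.16), the pyruvate dehydrogenase kinase Pdk4 by 3.83 (-2.30 and 1.53) and the lipogenic factor Srebf1 by -2.75 (1.26 and -1.49). The herpesvirus probe mghv-miR-M1-3-3p was brighter at MCT 270 by 1.29 ± 0.27 (limma adjusted p = 0.0113), while the other arm, mghv-miR-M1-3-5p, was dimmer (-1.47, adjusted p = 0.0201), as was mghv-miR-M1-6-5p (-0.82, 0.0361).

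Other splits of the 6 miRNA arrays were counted for each comparison. Of 10 splits, 1, the real one, reached its own count: 131 at MCT 270, 26 at MCT 330 and 30 between the doses, with a highest other count of 0 in each. The splits are too few for a share under 0.05. Every other split mixes both groups, so a real difference between them widens its spread and lowers its count. The counts of 0 therefore do not measure how many calls would arise by chance.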

How the results depend on the processing

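The agreement of the doses (r 0.567 to 0.602 over its alternatives), the family correlations and all named genes and called lists kept their direction under every alternative run for them. These kept each gene's brightest probe; another probe of Nkg7, Sctr, Ggps1 and Cd2 moved the other way. Of other values, 4476 for genes, 862 for lists and 740 for miRNAs kept their side of the threshold, 421, 179 and 187 lost it and 131 for genes gained it. Except where stated, the cause was not tested. Fits of 9 arrays count indistinguishable arrays as samples. Those with scan day or slide as a block were planned; the other fits of 9 arrays, the random block, results within slide 1, averaged miRNA arrays and the averaged samples left out were made alternatives after seeing the data. Signal near background limits dim genes, for which bounds are given.

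The count of changed mRNA genes at MCT 270 was 0; it was 519 with normexp and quantile normalization, 411 with genes well above background on all 9 arrays, 976 with a trended robust variance, 8787 with scan day as a block, 4725 with slide as a block, 9544 with 9 arrays, 9337 with 9 arrays and the replicate block, and 2822 with the independent sample as a random block. Within slide 1 it was 0, and each array left out gave 0 to 0. At MCT 330 the count was 3613 without a filter, 4905 with only the 2 groups, 17654 with scan day, 18760 with slide as a random block, 18051 with 9 arrays, 17917 with these and the replicate block, 10115 with the random sample block and 4905 without the sample of MCT 270 replicates 2 and 3; each array left out gave 4905 to 8410. Between the doses it was 0 without a filter, 0 with the replicate block, 15623 with scan day, 16964 with slide, 16109 with 9 arrays, 15949 with these and the replicate block, 7337 with the random sample block and 0 without the sample of MCT 270 replicates 2 and 3; each array left out gave 0 to 7284. Leaving out MCT 270 replicate 1 gave 4905 and 0.

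With an estimated correlation camera called 0, 0 and 0 lists in the 3 comparisons, and with 9 arrays 0, 0 and 2. Other alternatives gave 13 to 17, 22 to 27 and 18 to 27 lists, and 15 within slide 1; each array left out gave 16 to 17, 24 to 27 and 21 to 23.

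With replicates 2 and 3 of each group averaged 26, 12 and 0 miRNAs passed in the 3 comparisons, and with arrays averaged as on the mRNA platform 0, 0 and 0. For miRNAs at MCT 270, 86 passed with probes at 30 or more on all 9 arrays, and each array left out gave 28 to 143. At MCT 330, 13 passed with that filter and 46 with a trended robust variance, and each array left out gave 12 to 76 (13 without control replicate 1, 12 without control replicate 2, 16, 13 and 76 without MCT 330 replicates 1, 2 and 3). Between the doses, 70 passed with the authors' normalized values, 56 with foreground alone, 16 with that filter, 64 with the trended robust variance, 12 with only the 2 groups and 15 with the replicate block; each array left out gave 2 to 57 (5 without control replicate 2, 19 and 8 without MCT 270 replicates 1 and 3, 2, 2 and 57 without MCT 330 replicates 1, 2 and 3).

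Replicate numbers did not pair the arrays in every pair of groups. Deviations correlated best with those of the same number for 2 of 3 mRNA arrays between control and MCT 270. Between control and MCT 330 this held for 0, and between MCT 270 and MCT 330 for 3. The latter correlations were small (0.0425, 0.0546 and 0.0467), against at most 0.0144 for other numbers. For miRNA arrays the counts were 2, 0 and 1. Deviations of samples with the same number correlated at 0.0154 between control and MCT 270 for mRNA, and for miRNA at 0.105, 0.542 and 0.0527 (control and MCT 270), -0.223, 0.0457 and -0.383 (control and MCT 330) and 0.243, 0.212 and 0.0515 (MCT 270 and MCT 330). The replicate block gave 0, 6603 and 0 mRNA genes, 13, 24 and 20 lists, and 18 and 15 miRNAs in the 330 mg/kg comparisons.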

Other observations

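Some erythroid genes differed at MCT 330 without a call of their list, and erythroid and myeloid miRNAs passed only adjusted over their own lists. The haemoglobin gene Hbb-bs rose by a log2 fold change of 4.50 ± 0.89 (1 sample against 2; limma adjusted p = 0.0233), and it lay at 1.94 ± 0.73 at MCT 270. Of the other members of the erythroid list 3 fell, the carbonic anhydrase Car1 at -2.56 ± 0.40, Tspo2 at -1.43 ± 0.29 and the erythroid factor Klf1 at -0.99 ± 0.27. The erythroid list was not called (1 of 13 members rose and 3 fell, camera adjusted p = 0.497). Of 3 erythroid-enriched miRNAs, 3 were higher adjusted over the list alone and 0 over all miRNAs, with miR-144-3p at 1.95 ± 0.54, miR-451a at 1.30 ± 0.35 (limma adjusted p = 0.0597) and miR-144-5p at 1.29 ± 0.33 (n = 3 and 3). Of 4 myeloid-enriched miRNAs, 3 were higher adjusted over the list alone and 0 over all miRNAs: miR-223-3p at 1.23 ± 0.40 (limma adjusted p = 0.0990), miR-142-5p at 1.03 and miR-142-3p at 0.94, while miR-146a-5p lay at -0.78. Blood left in the tissue was not measured.

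Lymphocyte, duct and cell cycle genes moved both ways at MCT 330, and none of these lists was called by camera. Of 45 cell cycle genes 6 rose and 5 fell (camera adjusted p = 0.497): the mitotic cyclin Ccnb1 (-3.13 ± 0.31), Mcm10 (-2.74 ± 0.22) and thymidine kinase Tk1 (-2.40 ± 0.25) fell, while the replication helicase gene Mcm2 rose by 2.42 ± 0.35. Of 19 T cell markers 3 rose and 4 fell (adjusted p = 0.323), with the interleukin receptor Il7r at 2.11 ± 0.39, Cd4 at -1.85 ± 0.26 and Cd3e at -1.08 ± 0.20. Of 13 B and plasma cell markers 3 rose and 2 fell (adjusted p = 0.249), with Cd79b at 1.34 and Jchain at -1.43, and of 13 NK cell markers 1 rose and 1 fell (adjusted p = 0.241), Ncr1 at 1.36 and Nkg7 at -1.13. Of 20 cholangiocyte and progenitor markers 4 rose and 4 fell (adjusted p = 0.241), with Cd24a at 2.37 ± 0.28 and the mucin Muc1 at -2.06.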
